A study of Mus musculus with 12 samples.

How the data were processed

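Neurons derived from the mouse embryonic stem cell line D3 were measured at day 16 of differentiation, per the labels. Differentiation ran through embryoid bodies, aggregates formed in suspension after removal of the self-renewal factor LIF, per the labels' protocols. The samples were unmodified D3 cells, a line with a scrambled sequence (siSCR) and lines with knockdown of PRMT1 (siPRMT1) or PRMT8 (siPRMT8), with 3 biological replicates each. The labels do not say whether replicates came from separate differentiations, so p-values measure the spread between these cultures. Each group is 1 line, so effects of a line's history and of its knockdown are not separated. Total RNA was extracted with silica columns, and biotin-labelled single-stranded cDNA was made from it and hybridised to whole-transcript arrays with 1 colour, per the labels' protocols.

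The deposited table held 1 log2 value per probe set and array, 35556 probe sets for 12 arrays. The log2 scale was read from the values, which spanned 0.97 to 13.54. The background correction, summarisation and normalisation that the authors used are not given in the sources used here. The array medians differed by at most 0.023, and no normalisation was added. The spread differed more, with interquartile ranges of 2.89 to 3.04 in the knockdown and 3.06 to 3.13 in the control arrays. Quantile normalisation was run as an alternative and gave 3117 and 3785 changed genes in siPRMT1 and siPRMT8 against siSCR, in place of 2801 and 3565. No scanner files were used here, so no background level or detection call could be set beside a value, and levels of different probe sets are not comparable with each other. The labels name no hybridisation batch or date, so a batch that followed the lines could not be examined. No pair of arrays was identical (Pearson r over the tested genes 0.945 to 0.997).

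Probe sets were named through the platform's annotation table. Of the 35556, 21789 had 1 gene symbol, 1621 had several and 12146 had none there. The last 2 classes were left out of the gene tests. Symbols were updated by gene ID through the RefSeq gene table of assembly GRCm38.p6 (21698 matched, the rest kept the annotation's symbol). No coordinates are given because the array annotation names no build here. Where a symbol had more than 1 probe set (999 symbols), the one with the highest mean over all arrays was used, which left 19938 genes. Genes in the lowest 25% by mean value (below 5.43) were left out, which left 14953.

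Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model with the 4 groups as means and 8 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. SE is limma's moderated standard error. Each knockdown was compared with siSCR, siSCR with D3, and siPRMT1 with siPRMT8. The 29 gene lists (cell types, pathways and gene families) were written from general knowledge before the data were examined. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. For each list the members that passed over all genes and adjusted over the list alone were counted. On simulated data with 200 changed genes among 14953 for siPRMT1 against siSCR, the fit recovered 86.6% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes, with 11 false calls. The simulated noise was independent between genes and held no displaced array, so these rates apply to such data only.

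Named genes followed a rule set before the data were examined. The rule took Prmt1 and Prmt8, the 8 higher and 8 lower genes of each comparison with the largest fold change among those that passed and whose groups did not overlap, and up to 2 higher and 2 lower passing members of each list. Predicted genes, small RNAs and some gene families were counted but not named by it. Genes named outside the rule are marked where they appear.

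Both knockdown comparisons share the siSCR arrays. The chance level of their similarity was simulated 100 times with unchanged groups against shared controls, and the comparison was repeated with siSCR as the control of one knockdown and D3 of the other. Replicate numbers occur in every group. Whether they pair the arrays was checked by correlating, across genes, the deviations of same-numbered arrays from their group means. All 3 pairs lay above 0.1 for siSCR and D3 (0.107 to 0.194), so the fit with the number as a block is given beside that comparison where it moved the count. Over all groups 8 of 18 same-numbered pairs did, and 4 of 12 arrays had their best match outside the group at their own number. D3 replicate 2 with siSCR replicate 3 also reached 0.107, so pairing by number was not shown. Other alternatives were D3 or the mean of both controls, quantile normalisation, median centring, other filters, other uses of probe sets, 2-group fits, a trended robust variance, array weights, a 1.5-fold threshold and the omission of each replicate. The omission of siSCR replicate 1 together with siPRMT1 replicate 2, which stood apart on the first 2 principal components (61.4% and 15.7% of the variance), was added after seeing the data. So was the estimated correlation under other controls and omissions. Figures were drawn with matplotlib.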

Results

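Gene expression was measured in neurons derived from mouse D3 embryonic stem cells, collected at day 16 of differentiation, with 1-colour whole-transcript arrays. The 4 groups were unmodified D3 cells, a line that carried a scrambled sequence (siSCR), and lines with knockdown of the protein arginine methyltransferases PRMT1 (siPRMT1) or PRMT8 (siPRMT8). Each group had 3 biological replicates, so 12 arrays were compared, and their number limits the precision of every value. The deposited log2 values spanned 0.97 to 13.54, and the medians of the 12 arrays differed by at most 0.023. After the dimmest genes were left out, 14953 genes were tested. The first principal component held 61.4% of the variance. The D3 arrays lay at -22.7 to -21.6 on it and the 6 knockdown arrays at 13.6 to 25.7. siSCR replicates 2 and 3 lay at -26.2 and -22.2, with the D3 arrays, whereas siSCR replicate 1 lay at 0.105, between the control and the knockdown arrays.

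The targeted genes were examined first, in every array, to check the labels. Prmt1, which encodes the main asymmetric arginine methyltransferase of mammalian cells, read 7.72, 7.95 and 7.59 in the siPRMT1 arrays and 8.84, 8.74 and 8.86 in the siSCR arrays. It fell by 1.06 on the log2 scale (SE 0.0885, 2.09-fold, adjusted p = 0.000115, n = 3 per group, limma). In the siPRMT8 arrays Prmt1 read 9.27, 9.20 and 9.27, which was 0.43 above siSCR (SE 0.0885, 1.34-fold, adjusted p = 0.00625) and 0.49 above D3 (adjusted p = 0.00232). Prmt8, a membrane-anchored family member expressed mainly in brain, read 7.37, 7.41 and 7.40 in D3 and 6.60, 7.18 and 7.10 in siSCR. It read 6.35, 6.89 and 6.67 in siPRMT1 and 6.44, 6.17 and 6.44 in siPRMT8. In siPRMT8 it fell by 0.61 against siSCR (SE 0.157, 1.53-fold, adjusted p = 0.0171). That call was lost when siSCR replicate 2 (-0.50, adjusted p = 0.0728), siSCR replicate 3 (-0.54, adjusted p = 0.0712) or siPRMT8 replicate 2 (-0.52, adjusted p = 0.0599) was left out.

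Prmt8 was also low in the PRMT1 knockdown. It lay 0.32 below siSCR there, which did not pass (log2 -0.32, SE 0.157, adjusted p = 0.177), but against D3 it fell by 0.75 in siPRMT1 (adjusted p = 0.00488) and by 1.04 in siPRMT8 (adjusted p = 0.000993). The direct difference in Prmt8 between siPRMT1 and siPRMT8 was 0.29 (SE 0.157, adjusted p = 0.489). The change of -0.61 in siPRMT8 against siSCR was also smaller than the medians of pan-neuronal (-0.69) and synaptic genes (-1.05) there. The Prmt8 values thus do not show a PRMT8 knockdown apart from the fall of neuronal genes and of Prmt8 in siPRMT1. Of the other 7 family members measured, Prmt2 fell by 0.45 (SE 0.114, adjusted p = 0.0179) and Prmt5, the main symmetric arginine methyltransferase, rose by 0.20 (SE 0.0577, adjusted p = 0.0311) in siPRMT1 against siSCR. None of those 7 passed in siPRMT8 against siSCR, where Prmt2 lay at -0.33 (adjusted p = 0.055). In siPRMT1 against siPRMT8 neither Prmt2 (-0.12, adjusted p = 0.705) nor Prmt5 (0.11, adjusted p = 0.483) passed.

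**Figure D1:**
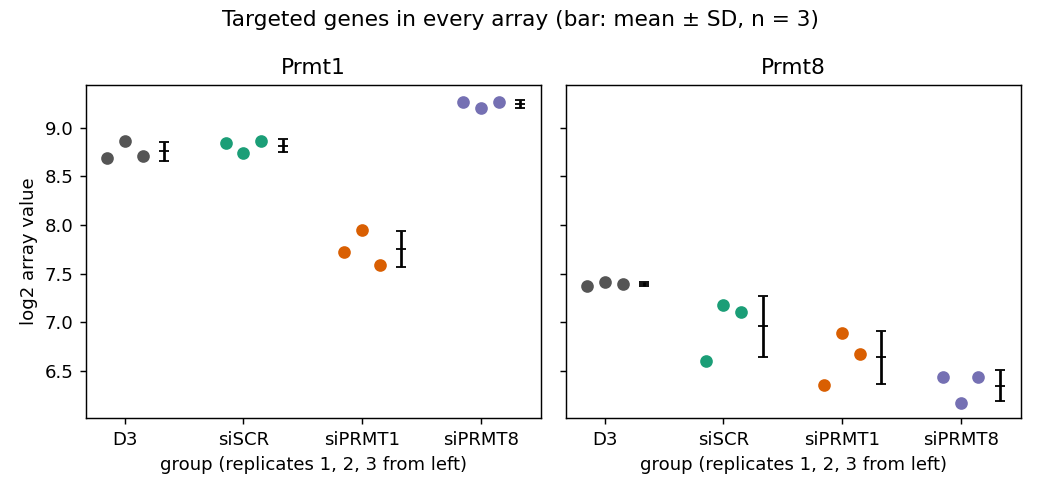
Log2 array values of Prmt1 and Prmt8 (vertical axis) in the 3 arrays of each of the 4 groups, with the group mean ± SD beside the points. The siPRMT1 arrays lie at 7.59 to 7.95 for Prmt1, below all others. For Prmt8 siSCR replicate 1 (6.60) lies among the siPRMT1 arrays (6.35 to 6.89) and above the siPRMT8 arrays (6.17 to 6.44).

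The comparison of siPRMT1 with siSCR asked what changes in these cultures when PRMT1 is knocked down. Each array read a whole culture. A fall of neuronal genes can therefore come from fewer neurons or from lower expression in them, which were not separated. The 4 neuronal lists lay lower with camera's preset correlation, but did not pass with an estimated one (adjusted p = 0.544 for pan-neuronal and synaptic genes and 0.576 for glutamatergic and GABAergic genes). Of 27 measured pan-neuronal genes 21 fell and 0 rose (21 lower and 1 higher adjusted over the list alone), with a median log2 change of -0.82. They included the axonal adhesion molecule L1cam (-1.63, SE 0.203, adjusted p = 0.000769) and the microtubule-binding protein Mapt (-1.48, SE 0.275, adjusted p = 0.00472). Of 29 synaptic genes 23 fell and 0 rose (24 and 0 adjusted over the list alone, median -1.11), among them the synaptic vesicle GTPase Rab3c (-1.99) and the vesicle protein Syt4 (-1.72). Of 16 glutamatergic genes 9 fell (10 adjusted over the list alone, median -0.74), led by the AMPA receptor subunit Gria2 (-2.08, SE 0.279, adjusted p = 0.00108) and the metabotropic receptor Grm5 (-1.79). Of 17 GABAergic genes 7 fell (10 adjusted over the list alone, median -0.35), led by Reln (-1.65), which encodes a secreted protein of some GABAergic neurons, and the neuropeptide gene Npy (-1.41). The same neuronal lists lay lower in siSCR replicate 1 than in siSCR replicates 2 and 3, with medians of -0.79 (pan-neuronal), -0.74 (synapse), -0.84 (glutamatergic) and -0.59 (GABAergic). The 9 glutamatergic genes were 5 without siSCR replicate 3. The 7 GABAergic genes were 3 without siSCR replicate 2 or 3, 11 against D3, and 12 with siSCR replicate 1 and siPRMT1 replicate 2 both left out.

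Hox genes and astrocyte genes also lay lower as lists in siPRMT1, and did not pass with an estimated correlation (adjusted p = 0.323 and 0.146). Of 24 measured Hox genes, the homeobox genes that mark position along the body axis, 20 fell and 0 rose (20 and 0 adjusted over the list alone, median -0.92). Hoxc5 (-1.56, SE 0.179, adjusted p = 0.000512) and Hoxa5 (-1.38, SE 0.196, adjusted p = 0.00144) changed most among the list members chosen for naming. Of 16 astrocyte genes 11 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.48). The glial intermediate filament gene Gfap fell 3.26-fold (log2 -1.71, SE 0.139, adjusted p = 0.000115), and by only 0.50 against D3 (log2 -0.50, adjusted p = 0.0214), because it was higher in siSCR than in D3. Sparcl1, a secreted glycoprotein of astrocytes, fell 4.78-fold (-2.26, SE 0.192, adjusted p = 0.000115) and by 1.93 against D3. The gap junction gene Gja1, which astrocytes share with progenitors and many other cells, rose 1.64-fold (0.71, SE 0.067, adjusted p = 0.000198). Of 21 mesenchymal and extracellular matrix genes 9 fell and 1 rose (10 and 1 adjusted over the list alone, median -0.20), led by the proteoglycan Dcn (-1.41) and Postn (-0.88). Hox genes lay 0.40 lower (median -0.40) and astrocyte genes 0.20 lower (median -0.20) in siSCR replicate 1 than in the other siSCR arrays. The 11 lower astrocyte genes were 7 without siSCR replicate 3. The 9 lower mesenchymal genes were 2 against D3, 4 or 3 without siSCR replicate 2 or 3, and 5 without siPRMT1 replicate 3.

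Of 29 cell cycle genes 8 rose and 0 fell (10 and 0 adjusted over the list alone, median 0.23), with the kinetochore genes Cenpf (0.58, SE 0.139, adjusted p = 0.0146) and Cenpe (0.55, SE 0.0855, adjusted p = 0.00213) first. This list lay 0.17 higher (median) in siSCR replicate 1 than in the other siSCR arrays, and 0.24 lower (median -0.24) in siPRMT1 replicate 2 than in the other siPRMT1 arrays. Its count of 8 was 14 against D3, 13 without siSCR replicate 1, 21 without siPRMT1 replicate 2, 3 or 2 without siSCR replicate 2 or 3, and 4 without siPRMT1 replicate 3. It was 25 with siSCR replicate 1 and siPRMT1 replicate 2 both left out, chosen after seeing the data. With camera's preset correlation of 0.01 these 8 lists passed in siPRMT1 against siSCR. The adjusted p was 2.83e-15 for Hox genes, 2.97e-14 for synapse, 2.58e-13 for pan-neuronal, 4.97e-05 for glutamatergic, 0.00174 for GABAergic, 3.4e-06 for astrocyte, 0.00387 for mesenchymal and 3.4e-06 for cell cycle genes. None passed with an estimated correlation, which was higher than the preset for all 8 lists. It was 0.635 for pan-neuronal, 0.599 for synapse, 0.456 for cell cycle, 0.452 for glutamatergic and 0.42 for Hox genes. GABAergic genes had 0.335, mesenchymal genes 0.186 and astrocyte genes 0.064. The adjusted p with an estimated correlation was then 0.323 for Hox genes, 0.146 for astrocyte genes, 0.544 for pan-neuronal and for synaptic genes, and 0.576 for glutamatergic, GABAergic, mesenchymal and cell cycle genes. With an estimated correlation and without siSCR replicate 1, chosen after the list tests were seen, synapse (adjusted p = 0.0335), Hox (0.0371) and pan-neuronal genes (0.0445) passed, and without siPRMT1 replicate 3 astrocyte genes did (0.0499). With both siSCR replicate 1 and siPRMT1 replicate 2 left out none passed (0.0503 or more). The mesenchymal list was also lost against D3 (median -0.12, adjusted p = 0.185) and without siSCR replicate 1 (median -0.15, adjusted p = 0.101).

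Single genes showed larger changes than any list median. The 8 higher genes with the largest separated changes were Fndc3c1 (4.29-fold, log2 2.10, SE 0.361, adjusted p = 0.00335), Prtg, Crabp2, Greb1l, Pga5, Trh, Pim2 and Igdcc3 (1.21, SE 0.231). Prtg, an immunoglobulin-family receptor of the early neural tube, rose 4.16-fold (2.06, SE 0.371, adjusted p = 0.00409), and Crabp2, a cellular retinoic acid binding protein, rose 2.90-fold (1.53, SE 0.307, adjusted p = 0.00658). The thyrotropin-releasing hormone gene Trh rose 2.48-fold (1.31, SE 0.181, adjusted p = 0.00123). The 8 lower genes were Serpina3n, Tac1, Scn2a, Sparcl1, Cacng3, Tmem130, Necab1 and Gria2. The serine protease inhibitor Serpina3n fell most, 6.44-fold (-2.69, SE 0.302, adjusted p = 0.000498), followed by the substance P precursor Tac1 (5.78-fold, -2.53, SE 0.606, adjusted p = 0.0148) and the voltage-gated sodium channel Scn2a (5.25-fold, -2.39, SE 0.378, adjusted p = 0.00228). Scn2a had 14 probe sets, and the mean of them fell by 1.61. Of the genes named by the rule that passed, 17 of 34 higher and 40 of 47 lower ones passed in the same direction against D3. Those that did not pass against D3 included Fndc3c1 (0.85, adjusted p = 0.103), Crabp2 (0.64, adjusted p = 0.145), Greb1l (0.71, adjusted p = 0.0732), Igdcc3 (0.28, adjusted p = 0.378) and Cenpf (0.28, adjusted p = 0.154). Prtg (1.35, adjusted p = 0.0203), Gja1 (0.43) and Cenpe (0.29) rose less against D3, and Hoxc5 fell less (-0.88).

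Of the lists that did not pass, several had members that changed. Of 19 proneural genes 3 rose, among them Neurod4 (1.15) and Nhlh1 (0.80), and 2 fell, Myt1 (-0.58) and Sox4 (-0.43). Against D3 0 proneural genes rose and 4 fell, with Nhlh1 at -0.35 (adjusted p = 0.24), and without siPRMT1 replicate 2 2 rose and 3 fell. Of 18 neural progenitor genes 2 rose, Lhx2 (0.58) and Prom1 (0.41), and 7 fell, led by Ptprz1 (-1.29) and the glutamate transporter Slc1a3 (-0.87). Of 19 retinoic acid response genes 3 rose, led by Crabp2 and Crabp1 (0.76), and 6 fell, led by Tshz1 (-1.20) and Tgm2 (-0.70). Of 23 hedgehog and patterning genes 4 rose, led by Pax3 (1.10) and Gli3 (0.73), and 6 fell, led by the ligand Shh (-1.10, SE 0.0935, adjusted p = 0.000115) and Hhip (-1.13), a target and inhibitor of the pathway. The adjusted p of these 4 lists was 0.321, except 0.662 for hedgehog and patterning genes. Neural progenitor genes passed as lower against D3 (median -0.23, adjusted p = 0.00337) and against the mean of siSCR and D3 (median -0.12, adjusted p = 0.0439), and proneural genes as higher without siPRMT1 replicate 1 (median 0.27, adjusted p = 0.0216). These 3 adjusted p were 0.365, 0.615 and 0.71 with an estimated correlation. Against D3 Neurod4 (0.055), Lhx2 (0.16), Prom1 (0.12), Crabp1 (0.28), Pax3 (0.18) and Gli3 (0.37) did not pass. Of 23 pluripotency genes 2 rose, Lin28a (1.09, SE 0.192, adjusted p = 0.00367) and Trim71 (0.47), and 21 did not pass (list adjusted p = 0.66, median -0.18). With siSCR replicate 1 and siPRMT1 replicate 2 both left out, chosen after seeing the data, that list's median was 0.28 (adjusted p = 0.0108, and 0.763 with an estimated correlation) and 8 members rose. Without siPRMT1 replicate 1 it passed the other way (median -0.37, adjusted p = 0.0353, and 0.797 with an estimated correlation). Against D3, or against siSCR without siPRMT1 replicate 2, 5 pluripotency genes rose and 0 fell. Hedgehog and patterning genes were 2 higher and 3 lower against D3, and 6 higher and 5 lower without siPRMT1 replicate 1.

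The other lists did not pass in this comparison either. Motor and other transmitter neuron genes (adjusted p = 0.51) included Isl1 (0.51) and the choline transporter Slc5a7 (0.45), which rose, and Phox2a (-0.65) and Lmx1b (-0.25), which fell. Neural crest genes (0.662) included Pax3 and Snai1 (0.28), which rose, and Tfap2a (-0.49), which fell. For other cell types the adjusted p was 0.987 for oligodendrocyte, 0.321 for endoderm, 0.321 for endothelial, 0.496 for epithelial, 0.734 for myeloid and 0.995 for muscle genes. Olig1, a transcription factor of the oligodendrocyte lineage, fell within its list (-0.92, SE 0.178, adjusted p = 0.00568), but did not pass against D3 (-0.25, adjusted p = 0.314). No member of the muscle, myeloid, ER stress and interferon lists passed. The adjusted p was 0.662 for p53 targets, 0.279 for ER stress, 0.352 for interferon, cholesterol and hypoxia genes, 0.257 for immediate early genes, 0.786 for the PRMT family and 0.995 for the FET family and ALS-linked genes. Of that last list Taf15, a FET family RNA-binding protein, rose (0.24, SE 0.0549, adjusted p = 0.0128) and Chmp2b fell (-0.51, SE 0.106, adjusted p = 0.00805). Against D3 Taf15 (0.15, adjusted p = 0.0639) and Snai1 (0.16, adjusted p = 0.145) did not pass. The hypoxia list passed without siPRMT1 replicate 3 (median -0.095, adjusted p = 0.0465, and 0.736 with an estimated correlation).

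In total 2801 of 14953 genes changed in siPRMT1 against siSCR (limma, adjusted p under 0.05), 1073 higher and 1728 lower. At 2-fold or more 18 were higher and 289 lower. The groups did not overlap in 4483 of the 14953 genes, where chance gives 10% for 3 against 3. The count was 357 when only these 2 groups were fitted, and 1318 or 1317 without siSCR replicate 2 or 3, which leaves siSCR replicate 1 as 1 of 2 controls, and 1771 without siPRMT1 replicate 3. It was 5077 with siSCR replicate 1 and siPRMT1 replicate 2 both left out, chosen after seeing the data.

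The comparison of siPRMT8 with siSCR asked the same of the siPRMT8 line. With the preset correlation 9 lists passed, the 8 of the first comparison and immediate early genes, and with an estimated one 0 did (adjusted p = 0.371 to 0.908 for the 9). Of the pan-neuronal genes 19 fell and 1 rose (21 and 1 adjusted over the list alone, median -0.69). L1cam (-1.65, SE 0.203, adjusted p = 0.000755) and Mapt (-1.52) fell, and the neurofilament gene Nefm rose 2.11-fold (1.08, SE 0.268, adjusted p = 0.0147). Of the synaptic genes 23 fell and 1 rose (23 and 1 adjusted over the list alone, median -1.05), with the scaffold gene Dlg2 (-1.62) and the vesicle glycoprotein Sv2a (-1.59) lowest among those named. The riser, Homer2 (0.24), did not pass as the mean of its 2 probe sets (0.10, adjusted p = 0.485). Of the glutamatergic genes 7 fell (9 adjusted over the list alone, median -0.53), led by Grm5 (-1.87) and Gria2 (-1.68). Of the GABAergic genes 6 fell (6 adjusted over the list alone, median -0.23), led by Reln (-1.50) and the receptor subunit Gabra2 (-0.91). As in the first comparison, these lists lay lower in siSCR replicate 1 than in the other controls. The 7 lower glutamatergic genes were 13 against D3, 12 with siSCR replicate 1 and siPRMT1 replicate 2 both left out, and 4 without siSCR replicate 2 or 3 or siPRMT8 replicate 1 or 3. The 6 GABAergic genes were 11 against D3, 12 with both arrays left out, and 3 without siSCR replicate 3 or siPRMT8 replicate 3.

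Hox genes fell in 20 of 24 (20 adjusted over the list alone, median -0.85), led by Hoxc5 (-1.52, SE 0.179, adjusted p = 0.000624) and Hoxc8 (-1.51, SE 0.168, adjusted p = 0.000479). Of the astrocyte genes 9 fell and 2 rose (11 and 2 adjusted over the list alone, median -0.48). Gfap fell 3.69-fold (-1.88, SE 0.139, adjusted p = 0.000206; -0.68 against D3, adjusted p = 0.00444) and Sparcl1 3.30-fold (-1.72), whereas Gja1 (0.77) and the transcriptional inhibitor Id3 (0.61) rose. Of the mesenchymal and extracellular matrix genes 9 fell and 3 rose (10 and 4 adjusted over the list alone, median -0.21), with Dcn (-1.16) and Postn (-0.87) lowest and Prrx1 (0.34) highest. Of the cell cycle genes 8 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.22), with the thymidylate synthase gene Tyms (0.66, SE 0.129, adjusted p = 0.00494) and Cenpe (0.54) first. The 8 cell cycle genes were 13 without siSCR replicate 1, 4 without siSCR replicate 3 or siPRMT8 replicate 1 or 3, 5 without siPRMT8 replicate 2, and 20 with siSCR replicate 1 and siPRMT1 replicate 2 both left out. The 9 lower mesenchymal genes were 3 against D3 or without siPRMT8 replicate 3, and 5 without siSCR replicate 1 or siPRMT8 replicate 1.

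Immediate early genes, which follow neuronal activity and other stimuli, passed as a list in siPRMT8 only among the 2 knockdowns, a difference that was tested directly and is given further on. Of 20 members 8 fell and 0 rose (10 and 0 adjusted over the list alone, median -0.26), led by Jund (-0.83, SE 0.0668, adjusted p = 0.000206) and the mRNA decay factor Zfp36 (-0.78). The count of 8 was 5 without siSCR replicate 1 or siPRMT8 replicate 2, 4 without siPRMT8 replicate 1, and 3 without siSCR replicate 2 or 3 or siPRMT8 replicate 3. Camera's adjusted p was 1.26e-13 for Hox genes, 1.42e-11 for synapse, 5.36e-10 for pan-neuronal, 0.000367 for glutamatergic, 0.025 for GABAergic, 0.000227 for astrocyte, 0.031 for mesenchymal, 0.000251 for cell cycle and 0.000373 for immediate early genes. None of the 9 passed with an estimated correlation. The adjusted p with an estimated correlation was 0.371 for astrocyte, 0.412 for Hox, 0.644 for immediate early, 0.663 for synapse, 0.674 for pan-neuronal, 0.804 for glutamatergic, 0.896 for mesenchymal and for cell cycle, and 0.908 for GABAergic genes. Without siSCR replicate 1, chosen after the list tests were seen, synapse and Hox genes passed with an estimated correlation (adjusted p = 0.0422 for both), and with siPRMT1 replicate 2 left out as well none did (0.0668 or more). The mesenchymal list was again lost against D3 (median -0.068, adjusted p = 0.535), against the mean of siSCR and D3 (adjusted p = 0.154), without siSCR replicate 1 (median -0.14, adjusted p = 0.325) and without siPRMT8 replicate 3 (adjusted p = 0.0617). The GABAergic list was lost without siSCR replicate 2 (adjusted p = 0.0596) or 3 (adjusted p = 0.108).

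The 8 higher genes with the largest separated changes in siPRMT8 were Fndc3c1 (6.20-fold, 2.63, SE 0.361, adjusted p = 0.0011), Prtg (4.89-fold), Crabp2 (4.10-fold), Pax3 (3.30-fold), Trh (3.05-fold), Greb1l (2.94-fold), Greb1 (2.85-fold) and Neurod4 (2.77-fold). Pax3 is a transcription factor of the dorsal neural tube and neural crest, and Neurod4 a proneural factor. The 8 lower genes were Serpina3n (6.82-fold, -2.77, SE 0.302, adjusted p = 0.000479), Cacng3 (5.94-fold), Tmem130 (4.77-fold), Atp1b2 (4.65-fold), Dazl (4.42-fold), Necab1 (4.23-fold), Dnmt3l (4.18-fold) and Elmod1 (4.15-fold). Cacng3 is an auxiliary subunit of AMPA receptors and Atp1b2 a subunit of the sodium pump. Dazl, a germ cell RNA-binding protein (-2.14, SE 0.552, adjusted p = 0.017), and Dnmt3l, a cofactor of DNA methyltransferases in germ and embryonic stem cells (-2.06, SE 0.689, adjusted p = 0.0487), varied widely between arrays. Dnmt3l read 6.55, 8.08 and 6.61 in siPRMT8, and did not pass against D3 (-1.77, adjusted p = 0.0775). Of the genes named by the rule that passed, 26 of 40 higher and 42 of 52 lower ones passed in the same direction against D3. Those that did not included Neurod4 (0.38, adjusted p = 0.31), Nefm (0.41, adjusted p = 0.285), Id3 (0.53, adjusted p = 0.0505) and Homer2 (0.017). Fndc3c1 (1.38), Crabp2 (1.14), Pax3 (0.80) and Greb1l (0.93) rose less against D3, and Hoxc5 (-0.83) and Hoxc8 (-0.91) fell less.

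The remaining lists did not pass in siPRMT8 against siSCR. Of the pluripotency genes 1 rose, Lin28a (0.88), and 3 fell, among them Dnmt3l and Klf5 (-0.46), with a list median of -0.33 (adjusted p = 0.113). The balance turned to 5 higher and 1 lower against D3 and to 2 higher and 1 lower without siSCR replicate 1, and 1 rose and 0 fell without siPRMT8 replicate 3. The count of 3 lower was 1 without siSCR replicate 2 or 3 or siPRMT8 replicate 1. With siSCR replicate 1 and siPRMT1 replicate 2 both left out 3 rose and 9 fell. Of the proneural genes 5 rose, led by Neurod4 (1.47) and Nhlh1 (1.05), and 1 fell, Neurod1 (-0.35), with adjusted p = 0.218. Against D3 1 proneural gene rose and 5 fell, with Nhlh1 at -0.091 (adjusted p = 0.783), and without siPRMT8 replicate 3 3 rose and 0 fell. Neural progenitor genes (adjusted p = 0.89) rose in 6 cases, among them Prom1 (0.64) and the Notch target Hes5 (0.55), and fell in 4, led by Ptprz1 (-0.92) and Slc1a3 (-0.74). That balance turned to 2 higher and 5 lower against D3, to 3 and 4 without siSCR replicate 3, and to 2 and 4 without siSCR replicate 2 or siPRMT8 replicate 1 or 3. Hes5 (0.038, adjusted p = 0.893) and Klf5 (-0.24, adjusted p = 0.254) did not pass against D3. Retinoic acid response genes (0.929) rose in 4 cases, led by Crabp2 and Crabp1 (0.99), and fell in 6, led by Tshz1 (-1.17) and Tgm2 (-0.80). Hedgehog and patterning genes (0.584) rose in 5 cases, led by Pax3 (1.72) and Gli3 (0.95), and fell in 6, led by Hhip (1.99-fold) and Shh (1.94-fold). Cholesterol synthesis genes (adjusted p = 0.1) rose in 5 cases, among them Idi1 (0.49) and Nsdhl (0.35), and fell in 1, the regulator Srebf2 (-0.17). The 5 were 2 against D3 or without siSCR replicate 3, 3 without siSCR replicate 2 and 1 without siPRMT8 replicate 3. Nsdhl did not pass against D3 (0.12, adjusted p = 0.38). The cholesterol list passed without siSCR replicate 2 (median 0.17, adjusted p = 0.0156) or siPRMT8 replicate 1 (median 0.16, adjusted p = 0.0355), and with an estimated correlation did not (0.833 and 0.827).

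Further lists gave adjusted p of 0.744 for the PRMT family, 0.937 for motor and other transmitter neuron genes, 0.584 for oligodendrocyte, 0.89 for neural crest, 0.929 for muscle, 0.945 for endoderm, 0.929 for endothelial, 0.89 for epithelial and 0.934 for myeloid genes. They gave 0.559 for p53 targets, 0.945 for ER stress, 0.228 for interferon, 0.744 for hypoxia and 0.89 for FET family and ALS-linked genes. Members that changed included Pecam1 of endothelial cells (-1.06), Cd68 of myeloid cells (-0.87), the calcium release channel Ryr2 (-0.85), Olig1 (-0.96), the angiogenic factor Vegfa (-0.45), Taf15 (0.19) and Hnrnpa2b1 (0.24). Of these Pecam1 (-0.76, adjusted p = 0.0995), Olig1 (-0.29, adjusted p = 0.256), Taf15 (0.10, adjusted p = 0.188) and Hnrnpa2b1 (0.16, adjusted p = 0.0917) did not pass against D3. In total 3565 genes changed, 1595 higher and 1970 lower. At 2-fold or more 34 were higher and 230 lower, and the groups did not overlap in 41.8% of genes, where chance gives 10%. The count was 1804 without siPRMT8 replicate 3, 1861 without siSCR replicate 3, 1996 without siSCR replicate 2, 2243 without siPRMT8 replicate 1, and 5710 with siSCR replicate 1 and siPRMT1 replicate 2 both left out, chosen after seeing the data.

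**Figure D2:**
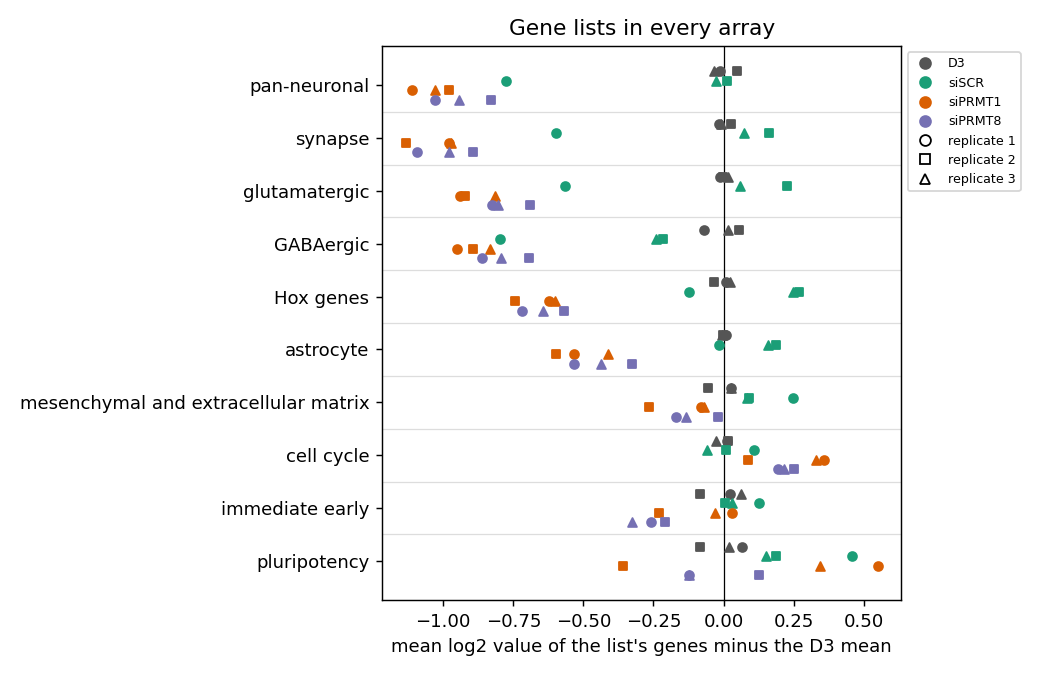
Mean log2 value of the genes of 10 lists in each array minus their mean in the D3 arrays (horizontal axis), with colours for the 4 groups and symbols for the replicates. All 6 knockdown arrays lie below the D3 arrays for the pan-neuronal list (-1.11 to -0.83), siSCR replicate 1 lies at -0.77, and for the pluripotency list siPRMT1 replicate 2 (-0.36) lies apart from siPRMT1 replicates 1 (0.55) and 3 (0.34).

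The 2 knockdowns were then set against each other gene by gene. Against the shared siSCR arrays, 723 genes rose in both and 1350 fell in both, where independent lists of those sizes would share 114 and 228. In opposite directions 3 genes changed, where 326 would by that reckoning, although shared controls themselves lower that number. These 3, named after their values were seen, were Prmt1, the chemerin receptor Cmklr1 (0.35 in siPRMT1, adjusted p = 0.0134, and -0.27 in siPRMT8, adjusted p = 0.036) and the syndecan Sdc2 (-0.23, adjusted p = 0.0363, and 0.20, adjusted p = 0.0482). Across genes, which are not independent replicates, the fold changes correlated with r = 0.88, and simulated unchanged groups with a shared control gave 0.50. The simulation drew every array with the same spread per gene, so it holds no displaced array such as siSCR replicate 1. The covariance was 0.0861, against 0.00604 in the simulation. With the controls split, siSCR for siPRMT1 and D3 for siPRMT8, r was 0.82 and the covariance 0.0887, and 2091 genes changed the same way and 30 in opposite ways. With D3 for siPRMT1 and siSCR for siPRMT8, r was 0.75 and the covariance 0.0844, and 1964 genes changed the same way and 21 in opposite ways. With siSCR replicate 1 and siPRMT1 replicate 2 both left out, chosen after seeing the data, these were 3631 and 37. The count of 2073 shared genes fell to 973 without siSCR replicate 2, 942 without siSCR replicate 3 and 1379 without siPRMT8 replicate 3. It was 631 when a 1.5-fold change was also required.

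**Figure D3:**
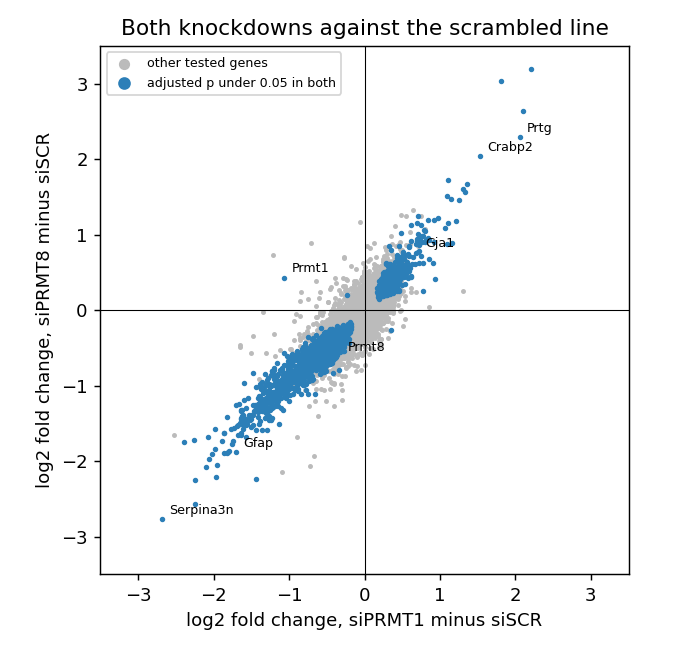
Log2 fold change of each of the 14953 tested genes in siPRMT1 (horizontal axis) and in siPRMT8 (vertical axis), both against siSCR, with genes that passed in both in blue. Of those, 723 lie upper right and 1350 lower left, and Prmt1 (-1.06 and 0.43) lies upper left. Because the siSCR arrays enter both axes, simulated unchanged groups, with the same spread per gene in every array, gave r = 0.50.

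The direct comparison of siPRMT1 with siPRMT8 asked where the 2 knockdowns differ. Among the genes that passed, Prmt1 itself was lowest in siPRMT1 relative to siPRMT8 (-1.49, SE 0.0885, 2.81-fold, adjusted p = 2.36e-05). The retinaldehyde dehydrogenase Aldh1a1 (-0.96, SE 0.135, adjusted p = 0.0214), the matrix protein Efemp1 (-0.82), Clca1 (-0.77), the axon guidance cue Sema3c (-0.59), the neural crest transcription factor Tfap2a (-0.59), the growth factor Pdgfc (-0.55) and Mgst1 (-0.50) were also lower in siPRMT1. Genes higher in siPRMT1 were the pepsinogen Pga5 (1.06, SE 0.108, adjusted p = 0.00407), Aspa (0.81), the endothelial GTPase Rhoj (0.74), Reep6 (0.64), Cmklr1 (0.62), the lysine methyltransferase Setd7 (0.60), Fndc1 (0.59) and the angiotensin receptor Agtr1a (0.52). In all 23 genes differed, 13 higher and 10 lower in siPRMT1, and 1824 had an unadjusted p under 0.05.

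By list, immediate early genes were higher in siPRMT1 than in siPRMT8 (median 0.19, adjusted p = 0.000529, adjusted p = 0.585 with an estimated correlation). Of them 1 gene passed alone, Jund (0.42, SE 0.0668, adjusted p = 0.0417), and 4 adjusted over the list alone. Pluripotency (median 0.18, adjusted p = 0.0377, 0 of 23 genes passing) and endoderm genes (median 0.16, adjusted p = 0.0377, 0 of 15) were higher. Neural progenitor (median -0.14, adjusted p = 0.00187, 0 of 18) and interferon response genes (median -0.22, adjusted p = 0.000818, 0 of 17, 5 lower adjusted over the list alone) were lower. With an estimated correlation the adjusted p was 0.94 for pluripotency, 0.697 for endoderm, 0.585 for neural progenitor and 0.587 for interferon genes. None of the pan-neuronal (adjusted p = 0.177), synapse (0.543), Hox (0.952), astrocyte (0.18) and cell cycle (0.439) lists passed between the knockdowns. The remaining 19 lists gave adjusted p from 0.07 to 0.952. The pluripotency list was lost without siPRMT1 replicate 1 (adjusted p = 0.969) or 3 (0.155) or siPRMT8 replicate 1 (0.0934) or 3 (0.109). The endoderm list was lost without siPRMT1 replicate 2 (0.184) or siPRMT8 replicate 2 (0.0968) or 3 (0.109), the progenitor list without siPRMT1 replicate 1 (0.0723) and the interferon list without siPRMT1 replicate 2 (0.184). Cell cycle (median 0.14, adjusted p = 0.00145), proneural (-0.21, adjusted p = 0.00593) and retinoic acid response genes (-0.18, adjusted p = 0.0131) passed without siPRMT1 replicate 2, and ER stress (0.076, adjusted p = 0.0283), oligodendrocyte and motor neuron genes without siPRMT1 replicate 1. These adjusted p were 0.91, 0.598 and 0.341, and 0.589 for the last 3, with an estimated correlation. Pan-neuronal genes passed with siSCR replicate 1 and siPRMT1 replicate 2 both left out, chosen after seeing the data (median -0.14, adjusted p = 0.00651, and 0.815 with an estimated correlation). Astrocyte (-0.13, adjusted p = 0.0486) and hypoxia genes (-0.12, adjusted p = 0.0336) passed without siPRMT1 replicate 3, retinoic acid response genes also without siPRMT8 replicate 3, and ER stress genes also without siPRMT1 replicate 3 or siPRMT8 replicate 1 or 3. None of these passed with an estimated correlation (adjusted p = 0.514, 0.806, 0.546, and 0.545 to 0.818 for ER stress). siPRMT1 replicate 2 set these counts: without it 862 genes differed, 574 higher and 288 lower, including all 23 found with it, 6 immediate early and 6 pluripotency genes among the higher. Without siPRMT1 replicate 1 there were 6, without siPRMT1 replicate 3 there were 2, and without siPRMT8 replicate 1, 2 or 3 there were 9, 3 or 2.

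The scrambled line was compared with unmodified D3 cells for the background of the design. Calbindin and calretinin, calcium-binding proteins of some GABAergic neurons, were lower in siSCR, with Calb1 at -1.45 (SE 0.203, 2.74-fold, adjusted p = 0.0261) and Calb2 at -1.44 (SE 0.217, adjusted p = 0.037). Tfap2a (-1.21, SE 0.0965, adjusted p = 0.000607), the Hox cluster transcript Hoxaas2 (-0.92), the neural adhesion molecule Cntn3 (-0.73), Lmo1 (-0.62), Moxd1 (-0.62), Pid1 (-0.57) and the sensory neuron factor Pou4f1 (-0.56) were lower too. Higher were Aldh1a7 (1.30, SE 0.206, adjusted p = 0.0395), Gfap (1.21, SE 0.139, adjusted p = 0.0102), Ceacam1 (1.14), the glucagon gene Gcg (1.06, SE 0.0908, adjusted p = 0.000693), the retinol carrier Rbp4 (0.62), the retinoic acid receptor Rarg (0.58), the amino acid transporter Slc7a3 (0.56) and Actn3 (0.44). Rbp4 lay below siSCR and above D3 in both knockdowns (against D3, 0.34 in siPRMT1, adjusted p = 0.0138, and 0.36 in siPRMT8, adjusted p = 0.0102). Neither target passed, with Prmt1 at 0.061 (adjusted p = 0.877) and Prmt8 at -0.43 (SE 0.157, adjusted p = 0.388). In total 23 genes changed, 9 higher and 14 lower, and the groups did not overlap in 20.3% of genes, where chance gives 10%. With the replicate number as a block there were 15, of which 12 were among the 23.

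Of the 29 lists, 12 passed in siSCR against D3 with the preset correlation and 0 with an estimated one, where the adjusted p were 0.349 or more. Proneural factors and Notch ligands had the smallest p (median -0.30, adjusted p = 6.74e-09, 0 of 19 genes passing and 12 lower adjusted over the list alone), followed by GABAergic genes (median -0.31, adjusted p = 2.42e-05, 2 of 17 lower, and 0 without any 1 of the D3 arrays or siSCR replicate 3), pluripotency (median 0.26, adjusted p = 5.13e-05, 0 of 23) and epithelial genes (median 0.25, adjusted p = 0.000124, 0 of 17). Pan-neuronal (median -0.24, adjusted p = 0.000176), neural progenitor (-0.12, adjusted p = 0.000448), synapse (-0.11, adjusted p = 0.0444), cholesterol (-0.084, adjusted p = 0.0126) and neural crest genes (-0.052, adjusted p = 0.0457, 1 of 12 lower, unpassed at 0.0517 with the block) also lay lower. Hox (0.14, adjusted p = 0.0021), mesenchymal (0.10, adjusted p = 0.0171) and oligodendrocyte genes (0.11, adjusted p = 0.0232) lay higher. The 17 other lists gave adjusted p from 0.0646 to 0.923. siSCR replicate 1 set several of these values. Without it the median was -0.012 for pan-neuronal genes (adjusted p = 0.805), 0.12 for synapse genes (adjusted p = 0.000154) and 0.070 for glutamatergic genes (adjusted p = 0.0231), the last against -0.069 (adjusted p = 0.0646) with it, and the mesenchymal (adjusted p = 0.154) and cholesterol (adjusted p = 0.19) lists were lost. GABAergic genes moved to -0.12 (adjusted p = 0.00656), pluripotency to 0.16 (0.00597) and epithelial genes to 0.11 (0.0231), and Hox genes to 0.27 (8.54e-14). The epithelial call was lost with siPRMT1 replicate 2 left out of the fit as well (adjusted p = 0.0803). No list passed with an estimated correlation and without siSCR replicate 1 (0.098 or more). Without siSCR replicate 2 or 3 the Hox (adjusted p = 0.127 or 0.137) and neural crest lists (0.0989 or 0.124) were lost and the glutamatergic list passed as lower (0.000557 or 0.0117). The synapse list was lost without D3 replicate 2 (0.112) or 3 (0.0622), and the mesenchymal (0.112) and cholesterol lists (0.342) without D3 replicate 2. The neural crest list was also lost without D3 replicate 3 (0.0732), and the oligodendrocyte list without siSCR replicate 3 (0.133). Astrocyte genes passed without siSCR replicate 1 (median 0.087, adjusted p = 0.00597), motor neuron genes without siSCR replicate 3 (0.0281) and glutamatergic genes also without D3 replicate 1 (0.0436). These were 0.24, 0.602 and 0.809 with an estimated correlation, and the glutamatergic list gave 0.605 or 0.677 without siSCR replicate 2 or 3. The count of 23 was 2, 2 or 3 without D3 replicate 1, 2 or 3, and 11 or 6 without siSCR replicate 2 or 3.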

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

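The tests of wrong or swapped labels, of a graded response, of shared controls, of the share of neurons and of an earlier stage were chosen after the result was seen, and only the counts over other splits of the arrays were set before theirs.

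Among the 12146 probe sets with no gene symbol in the annotation, which no comparison above uses, 460 changed in siPRMT1 against siSCR (3.79%, limma) and 730 in siPRMT8 against siSCR (6.01%). In siSCR against D3 limma called 0 of them, with 650 at an unadjusted p under 0.05, and 0 in siPRMT1 against siPRMT8, with 1123. What these probe sets measure was not analysed here. Groups of 3 arrays were not tested for outlying values.

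siSCR replicate 1 lay between the control and the knockdown arrays. A wrong label, with RNA of a knockdown culture in its place, is argued against: over the 1074 genes raised in both knockdowns against D3 its median share of the shift was 0.438 (quartiles 0.235 and 0.632), and Prmt1 read 8.84, outside both knockdown groups. The other target is no clear guide. Prmt8 read 6.60, among the siPRMT1 arrays (6.35 to 6.89), above the siPRMT8 arrays (6.17 to 6.44) and below siSCR replicates 2 and 3 (7.18 and 7.10). The pan-neuronal list lay lower in this array as well (median -0.79), so low Prmt8 there need not mark a knockdown. A graded version of the whole knockdown response stays open, since over the 1762 lowered genes the median share was 0.601 (quartiles 0.393 and 0.780), a difference of 0.162 with overlapping quartiles. Among genes changed by at least 1.5-fold in both knockdowns the difference was 0.409 (47 raised, 0.259, and 809 lowered, 0.669), so the test depends on that threshold. No biological explanation was tested, since the design gives this array nothing apart from the other siSCR arrays.

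The 2 knockdowns changed largely the same genes in the same direction. Shared siSCR arrays as the whole cause are argued against, since with separate controls the lower of the 2 covariances was 0.0844 and simulated shared controls gave 0.00604. A lower share of neurons stays open. It was tested only in the form in which every other cell type, astrocytes included, is raised alike. In the 6 knockdown against the 6 control arrays the astrocyte list moved by -0.51 relative to 7 other non-neuronal lists. The parts were -0.53 for astrocyte genes and -0.017 for the others. The exact permutation p was 0.00216 (two-sided), and it treats single arrays as exchangeable although each group is 1 line. It therefore does not measure a difference between lines. The astrocyte list was picked after its fall was seen, so the p-value gives no support, and the test cannot address neurons and astrocytes falling together. The 7 lists were oligodendrocyte, mesenchymal, muscle, endoderm, endothelial, epithelial and myeloid genes, without pluripotency, progenitor or cell cycle genes. How far the cultures held those cell types was not measured, so the test does not decide on the share of neurons. An earlier stage of differentiation stays open, because the progenitor and proneural medians against D3 ran from -0.23 to 0.018 and neither bound was met, and so do a change in astrocytes, an effect common to both knockdowns, and a batch that followed the lines, which no label names. Of 100 drawn splits of the 12 arrays into 6 and 6 only the real one, 1 split, gave as many changed genes (5467, highest other 3651). That argues against a random grouping of single arrays. The splits treat replicates of a line as exchangeable, and each group is 1 line, so a chance difference between lines cannot be excluded.

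siPRMT1 replicate 2 lay nearer siPRMT8 replicates 1 and 3 than its own, with a Euclidean distance over all genes of 26.0 against 37.7 to their mean, whereas siPRMT8 replicate 2 lay nearer its own (17.4 against 22.3). Swapped labels are argued against, since Prmt1 was 1.25 higher in siPRMT8 replicate 2 than in siPRMT1 replicate 2, against 1.61 between the other arrays of the 2 groups. siPRMT1 replicates 1 and 3 with siPRMT8 replicate 2, set against the other 3 knockdown arrays, gave 676 changed genes, many more than the 23 of the real split, which points to a structure of the samples that the labels do not name. A shared day or handling of cultures could be its source, untested because no label gives one. No biological explanation was tested.

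Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. In siPRMT1 against siSCR 1 split, the real one, gave 2801 genes or more, and the highest other gave 765 (siSCR replicate 1 with siPRMT1 replicates 1 and 3). In siPRMT8 against siSCR 1 split gave 3565 or more and the highest other 0. For siSCR against D3 1 split gave 23 or more and the highest other 0, and for siPRMT1 against siPRMT8 2 splits did, the real one with 23 and the one with 676.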

How the results depend on the processing

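The omission of siSCR replicate 1 and siPRMT1 replicate 2 together, and the estimated correlation under other controls and omissions, were chosen after seeing the data, and all other alternatives were planned. Of the genes named by the rule that passed, 23 of 81 in siPRMT1 against siSCR, 47 of 92 in siPRMT8 against siSCR, 2 of 17 in siSCR against D3 and 2 of 17 in siPRMT1 against siPRMT8 kept their direction and side of the threshold under every alternative run. No detection call or background value was used here, so what signal over background limits could not be examined. A different pseudocount was not run because the table is on the log2 scale. The cause was not tested for any value below, except that omissions leave fewer arrays, 2-group fits have fewer degrees of freedom, a fold threshold removes small changes and a test of every probe set adjusts over more tests.

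With an estimated correlation 0 lists passed in each of the 4 comparisons, against 8, 9, 12 and 5, and also 0 when both arrays were left out or with another control. With single replicates out it was 0 as well, except 3 without siSCR replicate 1 and 1 without siPRMT1 replicate 3 in siPRMT1 against siSCR, and 2 without siSCR replicate 1 in siPRMT8 against siSCR. In siPRMT1 against siSCR 2801 genes became 4320 with the mean of siSCR and D3 as control, 357 with only the 2 groups, 5528 with array weights, 837 with 1.5-fold, 5077 with both arrays out, and 1317 to 3763 with single replicates out. The percentage of higher genes was 38.3 and became 52.7 with array weights, 51.2 with both arrays out, 16.2 with 2 groups and 7.89 with 1.5-fold. In siPRMT8 against siSCR 3565 became 5694 with array weights, 874 with 1.5-fold, 5710 with both arrays out, and 1804 to 4107 with single replicates out.

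In siSCR against D3 23 became 12 with the lower 50% of genes left out, 2 with every probe set, 9 with 2 groups, 279 with array weights, 15 with the replicate block, 12 with 1.5-fold, 152 with both arrays out, and 2 to 21 with single replicates out. In siPRMT1 against siPRMT8 23 became 2 with every probe set, 2 with 2 groups, 1046 with array weights, 14 with the block, 13 with 1.5-fold, 1901 with both arrays out, and 2 to 862 with single replicates out. The 2073 genes shared by the knockdowns became 631 with 1.5-fold, 3631 with both arrays out, and 942 to 2949 with single replicates out. Prmt8 in siPRMT8 ran from -0.79 to -0.50 with single replicates out.

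Results whose sign turned against D3 were Nhlh1 (-0.35 in siPRMT1, -0.091 in siPRMT8), Pdgfra (-0.11 in siPRMT1), Rbp4 (0.34 and 0.36) and Spint1 (0.044 in siPRMT8). Of these only Rbp4 passed there (limma, adjusted p = 0.0138 and 0.0102), and the calls of the others were lost. The sign of Rbp4 also turned with the mean control (0.027 and 0.044), without passing (limma, adjusted p = 0.803 and 0.688). With both arrays out the pluripotency list in siPRMT1 against siSCR had a median of 0.28. In siSCR against D3 the lists of synapse (0.12) and glutamatergic genes (0.070) reversed without siSCR replicate 1 and with both arrays out. Pan-neuronal genes lost their call in both settings, with a median of -0.012 that stayed negative although camera's direction turned. With single replicates out the medians ran from -0.42 to -0.012 for pan-neuronal, -0.21 to 0.12 for synapse and -0.32 to 0.070 for glutamatergic genes. With an estimated correlation and without siSCR replicate 1, neither synapse (0.12, camera, adjusted p = 0.24) nor pan-neuronal genes (-0.012, adjusted p = 0.928) passed.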

Other observations

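The values in this part were chosen after they were seen, and no hypothesis was tested on them. Array values of 3 genes of the pluripotent state at day 16 were as follows. The transcription factor Nanog read 10.9 ± 0.063 (SD, n = 3) in D3, 11.1 ± 0.049 in siSCR, 10.8 ± 0.43 in siPRMT1 and 10.8 ± 0.19 in siPRMT8. Pou5f1 read 9.64 ± 0.059, 10.2 ± 0.13, 10.3 ± 0.25 and 10.2 ± 0.014 in the same order, and Dppa5a 11.9 ± 0.096, 12.1 ± 0.15, 11.6 ± 0.91 and 11.6 ± 0.34. Of the 24 measured Hox genes, Hoxa2, Hoxa9, Hoxb1 and Hoxd9 did not pass in either knockdown against siSCR, with Hoxb1 at 0.235 (adjusted p = 0.169) and 0.16 (adjusted p = 0.332).

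siPRMT1 replicate 2 lay apart from siPRMT1 replicates 1 and 3 in the pluripotency list, whose median was 0.82 lower there (-0.82). Of its 23 members 21 lay below both other arrays, and Lin28a and Sall4 above both. Single genes that lay lower in that array were Dnmt3l (-3.04), Dazl (-2.45) and Mael (-2.44). Dnmt3l read 6.40 there and 6.55, 8.08 and 6.61 in siPRMT8 replicates 1, 2 and 3. Dazl read 5.13 there and 5.33, 6.36 and 5.46 in those siPRMT8 arrays, and Mael 6.92 and 7.61, 8.45 and 7.80. Low values of these genes were thus not particular to siPRMT1 replicate 2.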
